A study of Mus musculus with 6 samples.

How the data were processed

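RNA of 6 samples of 4T1 cells was measured on Affymetrix mouse arrays, 3 with control shRNA and 3 with NFAT1 shRNA, and groups and replicate numbers were taken from the labels. Per the labels' protocols, cells were collected after 10 days of selection, RNA was isolated with a column kit, and biotinylated cRNA was made from 200 ng of total RNA. The deposited values are log2 signals, which the authors made with RMA, per the submitters' processing notes. RMA subtracts background, normalizes arrays by quantiles and summarises the probes of a probe set, and its version was not given in the sources used here. Quantile normalization forces similar distributions on all arrays, so a shift of most transcripts in 1 direction would be hidden, and dim probe sets are compressed toward the background. The log2 scale was checked on the values, which ran from 1.80 to 14.22, with medians of 5.42 to 5.48.

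The table held 45037 probe sets and 0 control probe sets of the AFFX kind. Of these, 34945 had 1 gene symbol in the platform annotation, 932 had several, and 9160 are unnamed here. The gene table GRCm38.p6 was used only for names. It matched 34741 of the probe sets with 1 symbol by gene number, and 0 symbols changed. For each of 18193 genes the probe set with the highest mean over all 6 arrays was used. Other probe sets of a gene entered the test over probe sets and 1 alternative.

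Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without a filter on dim genes and without covariates, and p-values were adjusted by Benjamini-Hochberg. Changed means an adjusted p under 0.05, and at least 2-fold means in addition a log2 difference of at least 1. All p-values are 2-sided. For the 6 Nfatc2 probe sets an exact permutation test over the splits of 3 against 3 was added. The 30 gene lists were written from textbook knowledge, with 810 entries of which 762 were measured, and each list had at least 5 measured genes. They were tested with camera of limma at its preset correlation of 0.01, again with an estimated correlation, and with fry. Members were counted after adjustment over all genes and over the list alone. The tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took Nfatc2, the other NFAT genes and calcineurin subunits, and the 12 largest rises and 12 largest falls among changed genes. These had to have no overlap between groups and a mean signal of at least 6 in the higher group, and predicted genes were skipped. It also took up to 4 members each way of lists past the threshold or with at least 3 changed members, of which the text gives a part.

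The alternatives were filters on dim genes, other scaling, a trended and robust variance prior, array weights, the replicate number as a block, leaving out each array, the mean of a gene's probe sets, leaving out probe sets prone to cross-hybridisation, and a test against a log2 threshold of 0.25. Each was run by itself. Arrays have no read depth, and their number limits the precision. The tests were run on simulated data first, with 18193 genes at their measured means, of which 200 had a known change. With independent spread limma recovered 13.4% of log2 changes of 0.5, 79.1% of 1 and 98.5% of 2, with 7 false calls. With spread shared between genes as in the data these were 14.9%, 73.1% and 97.0%, with 12 false calls. This spread was redrawn at random over the arrays, 1 time, so it does not keep how far apart the real arrays of a group lay. False calls can thus be more frequent on the real arrays. A list of mitosis genes moved by 0.5 was found by camera with 1 and 2 other lists called in error. With the correlation estimated its adjusted p was 0.00216 with independent spread and 0.246 with shared spread. Mixing of arrays was computed on the linear scale with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, over 8862 genes with a signal of at least 7 on an array, with 2000 bootstrap resamples of genes. Nfatc2 on single arrays was set against 100000 draws of other probe sets within 0.5 of the same control signal. On 8862 simulated genes, with noise set by hand, a mixture and a log-scale midpoint were told apart.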

Results

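Gene expression was measured in 4T1 cells, a mouse mammary carcinoma line that grows as a tumour and metastasises in mice. The cells had received either a control shRNA vector or a vector expressing an shRNA against NFAT1. NFAT1 is a transcription factor that enters the nucleus when calcium activates the phosphatase calcineurin, and its gene is Nfatc2. The cells were collected after 10 days of selection, and 200 ng of total RNA from each sample was labelled for an Affymetrix array. Each group held 3 arrays, numbered 1 to 3. The comparison asks which transcripts differ between 4T1 cells with and without the NFAT1 shRNA. Values are log2 RMA signals, with array medians from 5.42 to 5.48, and differences are NFAT1 shRNA minus control. The number of arrays limits the precision of every value. The labels do not say whether the arrays of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

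Nfatc2, the targeted gene, was read by 6 probe sets, which did not all go one way. On 1439205_at the mean signal was 6.05 ± 0.13 in control cells and 5.29 ± 0.14 in NFAT1 shRNA cells (SD, n = 3 each), a difference of -0.76 ± 0.11 (SE) and a level 59.2% of control. The NFAT1 shRNA mean lay below the array medians, where RMA compresses differences, so the remaining level can be overstated. The 3 NFAT1 shRNA arrays read 5.15, 5.43 and 5.29 there, all below the control arrays at 6.05, 6.18 and 5.91. With limma this difference had an adjusted p of 0.0707 over all probe sets and 0.00171 over the 6 Nfatc2 probe sets. Its exact permutation p was 0.1 (2-sided), the smallest that 3 arrays against 3 can give. On 1426032_at, the probe set with the highest mean of the 6, the signal was 5.90 ± 0.03 in control cells and 6.25 ± 0.20 in NFAT1 shRNA cells (adjusted p = 0.251). In all, 4 of the 6 probe sets were lower in NFAT1 shRNA cells and 2 were higher. None passed the limma test over all probe sets, and 3 had an unadjusted p under 0.05. The adjusted p of 1439205_at ran from 0.0160 to 0.342 over the settings tried. It was under 0.05 in 3 of them, without NFAT1 shRNA 1 (0.0160), with array weights (0.0320) and with the replicate number as a block (0.0228), and from 0.127 to 0.342 without any other array. With array weights 1426032_at passed as well, as a rise of 0.43 (adjusted p = 0.0289 over genes). With the mean of the 6 probe sets Nfatc2 differed by -0.14. The part of the transcript that each probe set reads was not analysed here, so the arrays are named by their labels throughout.

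**Figure D1:**
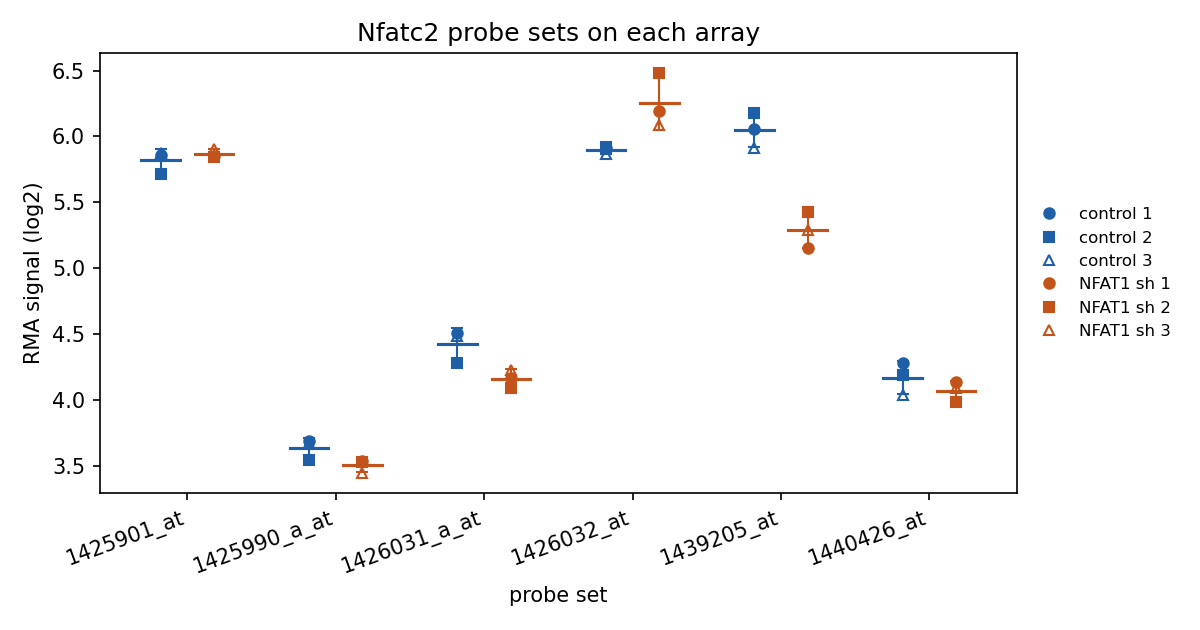
RMA signal (log2, vertical axis) of the 6 Nfatc2 probe sets (horizontal axis) on each array, with control arrays in blue and NFAT1 shRNA arrays in orange. Lines mark the mean and bars the SD of 3 arrays. On 1439205_at the NFAT1 shRNA arrays lie between 5.15 and 5.43, below the control arrays at 5.91 to 6.18.

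No other NFAT gene or calcineurin subunit passed the test over all genes. Nfat5, the NFAT family member that responds to osmotic stress, had a signal of 9.42 ± 0.20 in control cells and 10.34 ± 0.44 in NFAT1 shRNA cells (SD, n = 3; adjusted p = 0.159), and all 6 of its probe sets were higher. The differences were 0.16 for Nfatc1, -0.10 for Nfatc3 and -0.0014 for Nfatc4. Ppp3ca, a catalytic subunit of calcineurin, differed by 0.37 (adjusted p = 0.223). In other settings Nfat5 passed without NFAT1 shRNA 1 (1.17, adjusted p = 0.00572), without control 3 as well (0.0465), with array weights (0.0120) and with the replicate number as a block (0.0205), and Ppp3ca passed with array weights (0.0324). Nfatc1 differed by 0.41 without NFAT1 shRNA 1, where it passed (adjusted p = 0.0395), and by 0.0039 without NFAT1 shRNA 3. The other subunits Ppp3cb, Ppp3cc and Ppp3r1 differed by 0.11, -0.03 and -0.04. The sign turned in some settings for Nfatc1, Nfatc4, Ppp3cc and Ppp3r1, all with an adjusted p of at least 0.644 there. Of the 20 NFAT and calcineurin components, 0 passed with limma over all genes, and 5 had an unadjusted p under 0.05. Adjusted over the list alone, 2 were higher and 1 was lower. These were Nfat5, the calcineurin inhibitor Rcan1 (0.65) and the kinase Dyrk2 (-0.85). Of 28 genes listed as NFAT targets in the literature, 0 passed with limma over all genes and 6 had an unadjusted p under 0.05. Adjusted over the list alone, 1 was higher, the growth factor gene Csf2 (1.59). Neither list passed the camera test (adjusted p = 0.478 for the components and 0.608 for the targets), while fry's test for change in either direction called both (0.0211 and 0.0301).

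Across the transcriptome, 93 of 18193 genes changed, 33 upward and 60 downward. This balance depended on the setting: rises outnumbered falls without NFAT1 shRNA 1 (1922 against 1427), without control 3 as well (228 against 179), with array weights (1822 against 1558) and with the replicate number as a block (417 against 375). Among the 12 largest rises with a mean signal of at least 6 in NFAT1 shRNA cells, Eya2, a transcriptional coactivator and phosphatase, rose by 2.32 ± 0.32 (SE, adjusted p = 0.0495), and Tnfrsf19, a receptor of the TNF receptor family, by 2.29 ± 0.32 (adjusted p = 0.0495). The changed genes Aqp1 (1.79) and Plac8 (1.21) rose by more than some of the 12 but were dimmer than that. The transcription factor gene Klf2 rose from 5.67 ± 0.36 to 7.89 ± 0.20 (SD, n = 3; adjusted p = 0.0193), a 4.65-fold difference. Nptx1, which encodes a secreted pentraxin, had the smallest adjusted p of all genes, 0.00457, with a rise of 1.89 ± 0.09 (SE). Dusp6, whose product inactivates the kinase ERK, rose from 9.79 ± 0.08 to 11.30 ± 0.16 (SD, n = 3; adjusted p = 0.0141). The urate oxidase gene Uox rose by 2.08 and the semaphorin gene Sema6d by 1.86, and the chemokine receptor gene Cxcr3 rose 4.01-fold. Hs3st1, a heparan sulfate sulfotransferase, rose by 1.73 and the metalloprotease gene Adamts9 by 1.45. Epsti1 rose by 1.22 and the scaffold gene Tanc2 by 1.20. Each of these 12 genes was higher on all 3 NFAT1 shRNA arrays than on any control array, which the rule for named genes required. With the mean of a gene's probe sets, Tnfrsf19 rose by 0.985, Epsti1 by 0.60 and Sema6d by 0.61, the last no longer passing (adjusted p = 0.0700), nor did Eya2 (0.0557). Eya2 and Tnfrsf19 did not pass with array medians subtracted (0.0508 each), and Sema6d and Epsti1 not with another quantile normalization (0.0558 and 0.0579). Without NFAT1 shRNA 3 Eya2, Tnfrsf19 and Hs3st1 did not pass (0.0993, 0.0868 and 0.0749). The control means of Eya2 (4.56), Tnfrsf19 (4.21), Uox (4.61), Sema6d (5.39) and Adamts9 (5.18) lay below the array medians, where RMA compresses differences, so these rises can be understated and their order is uncertain.

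Among the 12 largest falls with a mean signal of at least 6 in control cells, Ctsw, which encodes cathepsin W, fell by 2.36 ± 0.24 (SE, adjusted p = 0.0281). The changed genes Dcaf8l and Scn3a fell by 2.28 each but were dimmer than that. Dag1, which encodes the laminin receptor dystroglycan, fell from 11.08 ± 0.20 to 9.38 ± 0.17 (SD, n = 3; adjusted p = 0.0155), and all 4 of its probe sets were lower. Moxd1, a monooxygenase gene, fell from 10.50 ± 0.03 to 8.62 ± 0.26 (SD, n = 3; adjusted p = 0.0141). Abcg2, a drug efflux transporter, fell from 8.91 ± 0.06 to 7.40 ± 0.21 (SD, n = 3; adjusted p = 0.0155), a 2.85-fold difference. Armcx4 fell by 2.13, the nucleosome-binding gene Hmgn5 fell by 2.10 and the serine protease gene Prss23 fell by 2.07. Rtca, an RNA cyclase, fell by 1.60 and Donson, which acts at replication forks, fell by 1.55. Asb4 fell by 1.55, Lrrc40 fell by 1.49 and the methyltransferase gene Carnmt1 fell by 1.46. Each of the 12 was lower on all 3 NFAT1 shRNA arrays than on any control array, which the same rule required. With the mean of a gene's probe sets Donson fell by 0.86 and Asb4 did not pass (adjusted p = 0.0595). Without probe sets prone to cross-hybridisation Prss23 fell by 1.37 (adjusted p = 0.0866). Without NFAT1 shRNA 3 Hmgn5, Rtca, Donson, Asb4 and Lrrc40 did not pass (adjusted p from 0.0553 to 0.0868). The NFAT1 shRNA means of Armcx4 (4.63) and Asb4 (5.08) lay below the array medians. These falls can thus be understated and their order is uncertain.

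**Figure D2:**
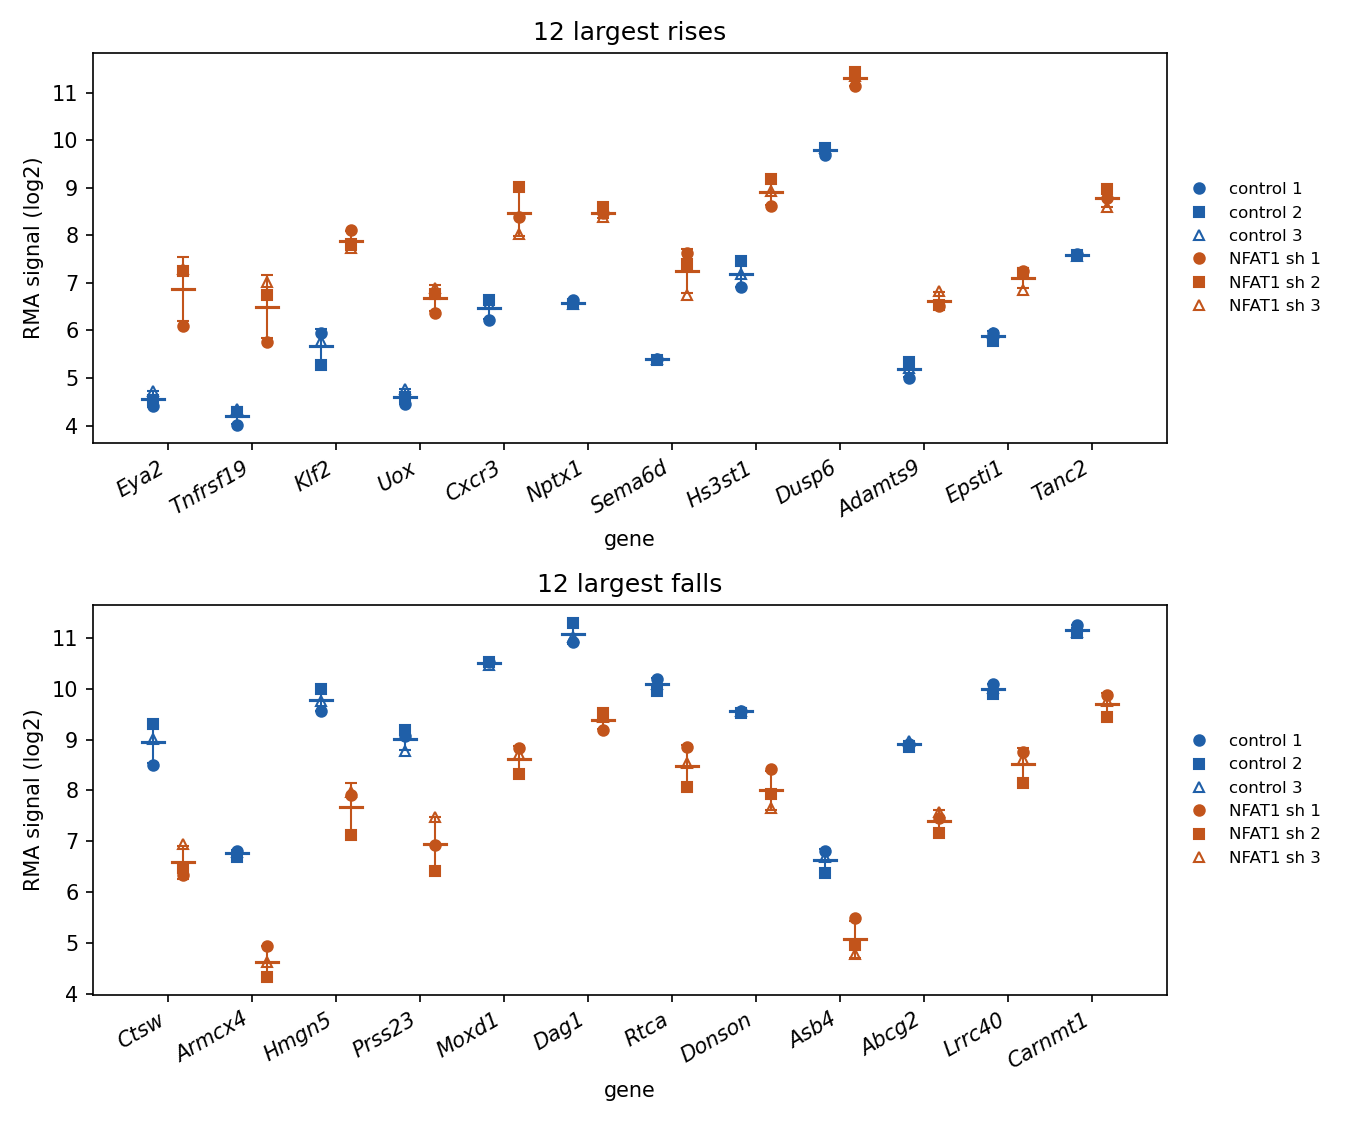
RMA signal (log2, vertical axis) on each array of the 12 genes with the largest rise (top) and the 12 with the largest fall (bottom). All are changed genes with a mean signal of at least 6 in the higher group. Control arrays are blue and NFAT1 shRNA arrays orange, lines mark the mean and bars the SD of 3 arrays. The groups do not overlap for any of the 24 genes, which the rule for named genes required, and Dusp6 lies near 9.79 in control cells and 11.30 in NFAT1 shRNA cells.

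The counts come from limma with an adjusted p under 0.05. Of the 93 changed genes, 44 differed at least 2-fold, 18 upward and 26 downward. An unadjusted p under 0.05 was found for 3115 genes, where chance gives 910 if all arrays vary independently. The groups did not overlap for 22.8% of all genes, where chance gives 10% on the same condition, and for all 93 changed genes. Control 3 did not meet this condition, as it lay between controls 1 and 2 for all 199 genes examined below. Both chance figures can therefore be too low, and genes are not independent of each other. Neither comparison can thus decide whether the groups differ by more than chance. Of the 60 changed genes with more than 1 probe set, 52 had all probe sets in 1 direction. Tested by probe set, 90 of 45037 passed, 34 higher and 56 lower, of which 3 were unnamed here. The count of changed genes was 3380 with array weights and 792 with the replicate number as a block. The counts depended on single arrays: with limma 0 genes passed without control 1, control 2 or control 3 (1698, 2247 and 1761 had an unadjusted p under 0.05), 2 without NFAT1 shRNA 2 (Nptx1 and Moxd1) and 3349 without NFAT1 shRNA 1. The counts changed at least 2-fold were then 0, 0, 0, 2 and 672, and those of probe sets 0, 0, 0, 0 and 5794, with 3992, 5086, 4251 and 4290 probe sets at an unadjusted p under 0.05 beside the zeros.

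The arrays of a group were not equally far apart. Control 3 lay between controls 1 and 2 for 199 of the 199 genes with a range of at least 2-fold over the 3 controls and a signal of at least 7 on an array. That is 100% (exact 95% interval 98.2% to 100%, genes not being independent), where arrays that vary independently in each gene give 33.3% for each array of a group. Of 1093 genes chosen in this way on the NFAT1 shRNA arrays, NFAT1 shRNA 1, 2 and 3 lay in the middle for 5.31%, 48.4% and 46.3%. NFAT1 shRNA 1 correlated with the controls at 0.991 to 0.995 across probe sets, and with NFAT1 shRNA 2 and 3 at 0.986 and 0.985. Leaving out control 3 and NFAT1 shRNA 1 together, a setting chosen after the data were seen, gave 407 changed genes, 58 of them among the 93. It gave 263 genes changed at least 2-fold and 0 changed probe sets with limma, with 9273 at an unadjusted p under 0.05.

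**Figure D3:**
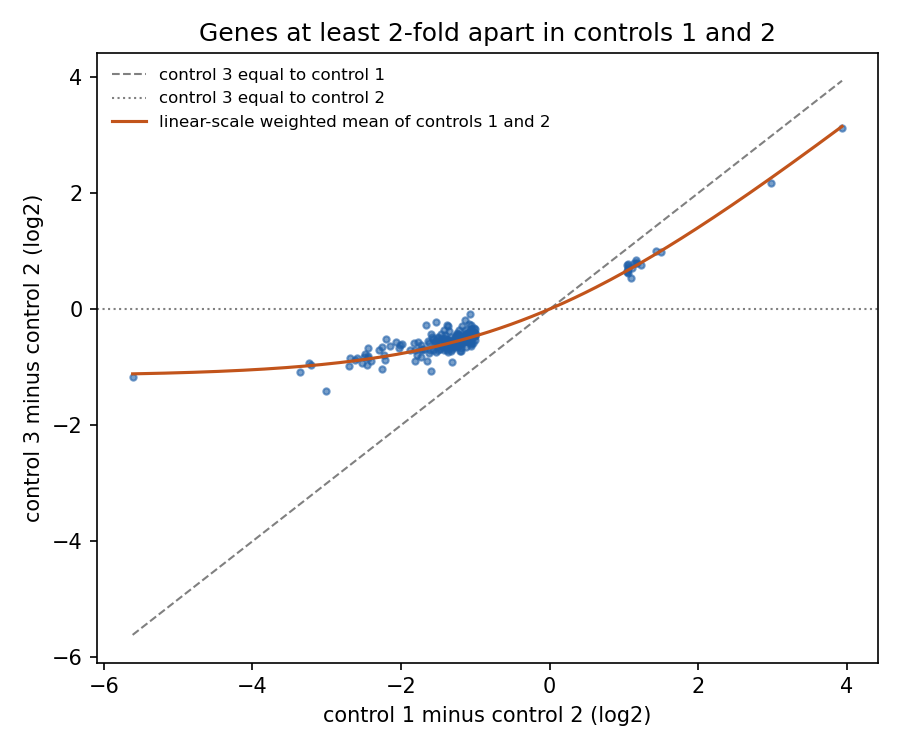
Control 3 minus control 2 (log2, vertical axis) against control 1 minus control 2 (log2, horizontal axis) for the 199 genes at least 2-fold apart in controls 1 and 2 with a signal of at least 7 on an array, 1 point per gene. All points lie between the dashed line, where control 3 equals control 1, and the dotted line, where it equals control 2, and the curve is the linear-scale weighted mean with 55% of control 1.

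Cell cycle genes formed the list with the smallest camera p. Of 33 mitosis genes, 31 had a lower mean signal in NFAT1 shRNA cells, with a median difference of -0.31. None passed with limma over all genes, 15 were lower with an unadjusted p under 0.05, and 7 were lower adjusted over the list alone. The list was lower with an adjusted p of 1.2e-11 by camera, and had an adjusted p = 0.682 with an estimated correlation. The spindle assembly gene Tpx2 differed by -0.60 (adjusted p = 0.0568), the mitotic kinase gene Aurka by -0.86 (adjusted p = 0.0709) and the transcription factor gene Foxm1 by -0.55. Of 33 S phase and DNA replication genes, 32 had a lower mean, with a median difference of -0.30. In this list 0 passed with limma over all genes and 0 adjusted over the list alone, while 8 were lower with an unadjusted p under 0.05. Its camera adjusted p was 5.22e-08, against an adjusted p = 0.684 with an estimated correlation. Rrm2, which makes deoxyribonucleotides, differed by -1.03 and the thymidylate synthase gene Tyms by -1.06, and the helicase gene Mcm2 by -0.43. The S phase list was lower on NFAT1 shRNA 2 and 3 only, with medians of -0.56 and -0.53 against the control mean, and read 0.08 on NFAT1 shRNA 1.

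All 30 genes of the ribosome biogenesis and MYC target list had a lower mean in NFAT1 shRNA cells, with a median difference of -0.42. With limma 0 passed over all genes and 0 adjusted over the list alone, and 4 were lower with an unadjusted p under 0.05. The camera adjusted p was 2.35e-07, against an adjusted p = 0.684 with an estimated correlation. The nucleolar helicase gene Ddx21 differed by -0.86, the nucleolar gene Wdr12 by -0.61 and Cad, the first enzyme of pyrimidine synthesis, by -0.50. This list also differed between control arrays, with medians of 0.23, -0.23 and 0.03 against the control mean. The medians of NFAT1 shRNA 1, 2 and 3 were 0.11, -0.74 and -0.62.

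Lipid synthesis lists were lower as well by camera. Of 21 fatty acid synthesis genes, 1 fell over all genes, Gpam, the first enzyme of glycerolipid synthesis, by 0.72 ± 0.09 (SE, adjusted p = 0.0382). Gpam fell by 0.25 with the mean of its probe sets (adjusted p = 0.278), and it did not pass with a trended and robust variance prior (0.0615) or without NFAT1 shRNA 3 (0.0749). The other 20 did not pass. Adjusted over the list alone, 4 were lower and 1 was higher. Among these the elongase gene Elovl6 differed by -1.09 (adjusted p = 0.0512 over all genes), the desaturase gene Scd2 by -0.45 and the ligase gene Acsl4 by 0.66. The list had a camera adjusted p of 7.07e-05, and an adjusted p = 0.682 with an estimated correlation. Of 20 genes of cholesterol synthesis and SREBP2 targets, 15 had a lower mean. With limma 0 passed over all genes or adjusted over the list alone, and 9 were lower with an unadjusted p under 0.05. Srebf2, the transcription factor of this pathway, differed by -0.35, the synthesis gene Hsd17b7 by -1.42 and the isomerase gene Idi1 by -0.67. The camera adjusted p was 2.58e-05, against an adjusted p = 0.682 with an estimated correlation.

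The list of immediate early and MAPK feedback genes was higher by camera (adjusted p = 0.0171), and had an adjusted p = 0.682 with an estimated correlation. Of its 32 genes, 2 rose over all genes, Klf2 and Dusp6, 0 fell and 30 did not pass. Adjusted over the list alone, 5 were higher. The others were Spry2 (0.55, adjusted p = 0.0535 over all genes) and Spry1 (1.01), inhibitors of receptor tyrosine kinase signalling, and the early transcription factor gene Egr1 (2.62, adjusted p = 0.144 over all genes). The list's medians were 0.15, 0.0079 and 0.43 on NFAT1 shRNA 1 to 3, so NFAT1 shRNA 2 lay at the level of the controls (-0.0089, 0.015 and 0.0060). Its camera adjusted p was 0.0575 without NFAT1 shRNA 1 and 0.0729 without NFAT1 shRNA 3. Antigen presentation genes were higher by camera too (adjusted p = 0.0332, against an adjusted p = 0.684 with an estimated correlation), with 16 of 18 members at a higher mean. With limma 0 passed over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05. The immunoproteasome gene Psmb9 differed by 1.25, the class I regulator Nlrc5 by 0.88 and the class I heavy chain gene H2-D1 by 0.54. Their list read -0.24, 0.22 and 0.05 on the control arrays and 0.04, 0.57 and 0.61 on the NFAT1 shRNA arrays. Its camera adjusted p was 0.0895 without control 1, 0.134 without NFAT1 shRNA 2 and 0.0895 without NFAT1 shRNA 3.

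TGF-beta target genes were lower by camera (adjusted p = 0.0171), with an adjusted p = 0.682 with an estimated correlation and a median difference of -0.21 over 22 genes. Without NFAT1 shRNA 1 this median difference was -0.051. The list's medians were -0.22, -0.096 and 0.0015 on NFAT1 shRNA 1 to 3, so NFAT1 shRNA 3 lay within the range of the controls (0.015, 0.053 and -0.013). Of these 0 passed with limma over all genes or adjusted over the list alone, and 2 were higher and 4 lower with an unadjusted p under 0.05. Thbs1, which encodes the matrix protein thrombospondin, differed by -0.90, and the inhibitor of differentiation gene Id1 by -0.74 and Pmepa1 by -0.36. Of 29 unfolded protein response and ATF4 target genes, 0 passed with limma over all genes or adjusted over the list alone, and 4 were higher and 7 lower with an unadjusted p under 0.05. The list was lower by camera (adjusted p = 0.0206, and an adjusted p = 0.682 with an estimated correlation), with Sdf2l1 at -0.82 and the amino acid transporter gene Slc7a5 at -0.52, while the chaperone gene Dnajb9 differed by 0.61. Its medians were -0.17, -0.12 and 0.014 on NFAT1 shRNA 1 to 3, the last within the range of the controls (-0.0079, 0.032 and -0.0038), and its mean difference turned from -0.043 to 0.054 without NFAT1 shRNA 1. Integrin and focal adhesion genes were lower by camera (adjusted p = 0.0428, and an adjusted p = 0.682 with an estimated correlation). Of 28 measured, 0 passed with limma over all genes, 9 had an unadjusted p under 0.05, and 1 was higher and 1 lower adjusted over the list alone. These were the integrin genes Itga1 (1.87) and Itgb6 (-1.21), and the caveolin gene Cav1 differed by -0.82. The integrin list's medians were -0.11, -0.14 and -0.0135 on NFAT1 shRNA 1 to 3, against -0.0063, -0.0068 and 0.011 on the controls. Without NFAT1 shRNA 1, camera gave these 3 lists adjusted p-values of 0.393, 0.407 and 0.338, and without control 2 it gave 0.0855 for the unfolded protein response list and 0.0864 for the integrin list, which did not pass without NFAT1 shRNA 2 either. Array weights and both filters on dim genes ended the calls of all 3 lists (adjusted p from 0.118 to 0.254), and another quantile normalization ended the last 2 (0.148 and 0.301).

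**Figure D4:**
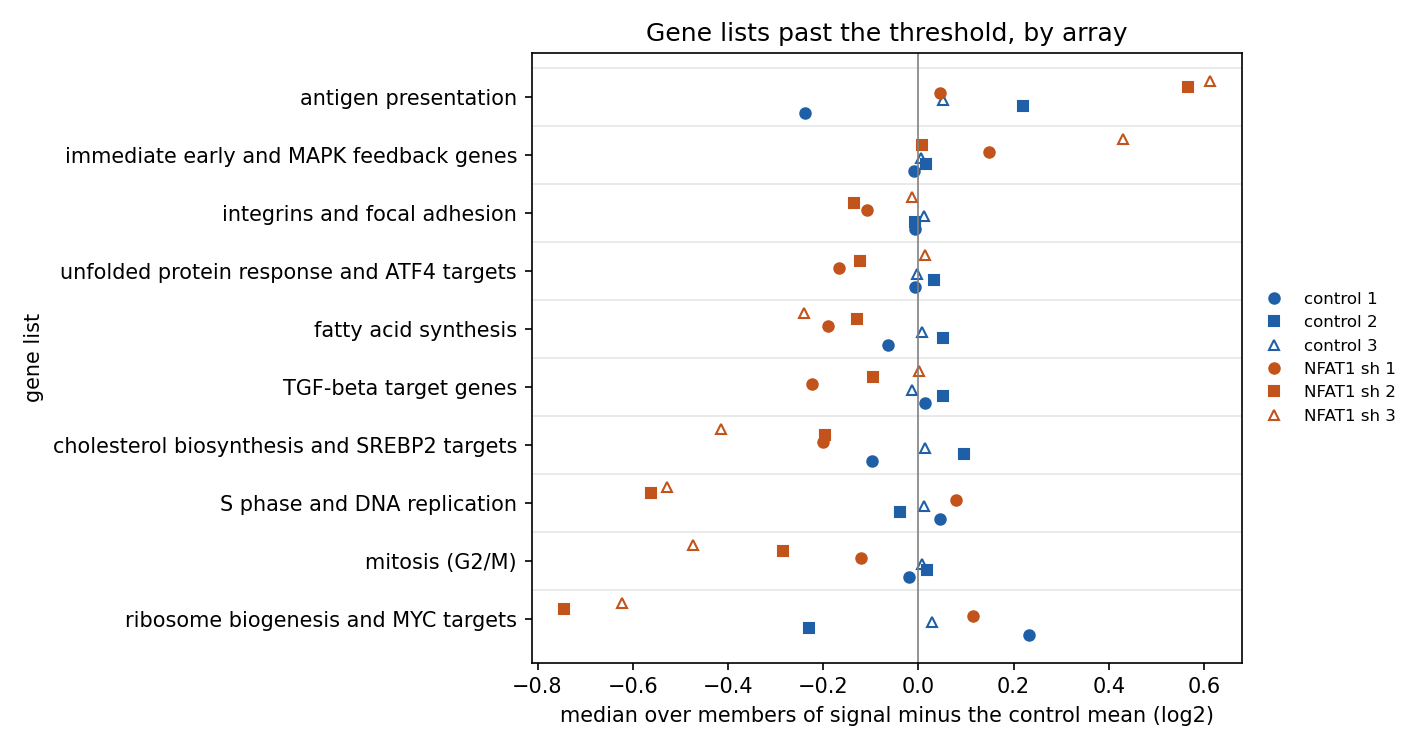
Median over the members of each gene list past the camera threshold (vertical axis) of the signal on an array minus the control mean (log2, horizontal axis), 1 point per array, with control arrays in blue and NFAT1 shRNA arrays in orange. S phase and ribosome biogenesis genes lie at 0.08 and 0.11 on NFAT1 shRNA 1, near the controls, and at -0.56 and -0.74 on NFAT1 shRNA 2.

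The other 20 lists did not pass camera, with adjusted p from 0.0623 to 0.905, and 1 of them held a gene that passed over all genes. This was the laminin gene Lamb3, of the extracellular matrix list, which fell by 0.83 ± 0.11 (SE, adjusted p = 0.0451). Lamb3 did not pass with the filters on dim genes (adjusted p = 0.0510 and 0.0504), with a trended and robust variance prior (0.0616) or without NFAT1 shRNA 3 (0.0974). Single members passed in 10 of these lists adjusted over the list alone, and were named after their values were seen. They included the matrix genes Postn (-2.66) and Fbln2 (-1.27), and among matrix proteases and inhibitors Adam12 (-1.94), Adamts1 (-2.07), Timp1 (-1.44) and Mmp3 (1.30), with 6 lower and 1 higher of 29. In the angiogenesis list 5 were lower and 2 higher of 28, among them Nrp1 (-2.03), Vegfc (-0.99) and Pdgfb (-1.10). Of 29 cytokine genes, Cxcl3 (-2.18) was lower and Csf2 and Tslp (1.25) were higher, and Csf2 was also the 1 of 26 NF-kB targets to pass. The kinase gene Axl (-1.21) was the 1 of 21 mesenchymal genes to pass and Wnt10a (-1.29) the 1 of 30 Wnt genes. Of 23 NRF2 targets and glutathione genes, Gstm2 (1.02) and Cbr3 (0.74) were higher and Taldo1 (-0.37) and Abcc1 (-0.43) lower. Apart from Lamb3, none of these genes passed over all genes. With limma 0 members passed in either way among epithelial markers (5 with an unadjusted p under 0.05), p53 targets (5), apoptosis regulators (5), type I interferon genes (1), hypoxia and glycolysis genes (6), RNA interference machinery (1) and mammary luminal genes (5). The same held for the markers of leukocytes and macrophages (23 measured), endothelium (16) and fibroblasts and pericytes (18), of which 0, 2 and 1 had an unadjusted p under 0.05 with limma. All 18 fibroblast and pericyte markers had a higher mean in NFAT1 shRNA cells, with a median difference of 0.13 (camera adjusted p = 0.104, unadjusted p = 0.0414). Over all genes the median difference was 0.043, and over those above the median signal it was 0.0069.

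Camera's preset correlation of 0.01 gave 10 of 30 lists past the threshold, 8 lower and 2 higher. With the correlation estimated for each list 0 passed (1 had an unadjusted p under 0.05), and with fry 0 passed (5 unadjusted), so that all 10 calls rest on the preset value. Fry's test for change in either direction called 15 lists. For the 10 lists past the threshold, the median, the mean and the camera direction had 1 sign. They differed in sign for 10 of the other lists: the extracellular matrix, protease, p53, interferon, NF-kB, Wnt, angiogenesis, hypoxia, NRF2 and RNA interference lists. Without NFAT1 shRNA 1 the number of lists past the threshold was 6, and without both that array and control 3 it was 6.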

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

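Leaving out control 3 with NFAT1 shRNA 1 was chosen after the data were seen. All 93 changed genes kept their sign in every setting that tested them. This was fixed in advance where arrays were left out or weighted, since the groups did not overlap for any of the 93. The filters, the variance prior, the block and the log2 threshold leave the differences as they were. Only other scaling or other probe sets could turn a sign. Of the 24 named rises and falls all that were tested (17 to 24) stayed past the threshold in 5 settings of the full set of arrays. In the other 5 such settings 22 of 24 passed with array medians subtracted and with another quantile normalization, 21 with the mean of probe sets, 22 of 23 without probe sets prone to cross-hybridisation and 12 with the test against a log2 threshold. With 1 array left out 24 passed without NFAT1 shRNA 1, 2 without NFAT1 shRNA 2, 16 without NFAT1 shRNA 3 and 0 without a control. Changed genes numbered 61 above the median signal (9096 genes tested), 3380 with array weights and 23 with the test against a log2 threshold. With the replicate number as a block they numbered 792. Same-numbered arrays deviated together with correlations of 0.619, 0.513 and 0.051, and NFAT1 shRNA 3 correlated best with control 2 (0.269). Since not every pair was over 0.1, the numbers were not taken to pair the arrays, but control 3 deviated little from the control mean and correlated with no NFAT1 shRNA array (-0.023 to 0.051), so its pair is uninformative and pairing stays open. The count was 0 to 3349 when 1 array was left out: 0 without any 1 of the controls (1698 to 2247 genes at an unadjusted p under 0.05 with limma), 2 without NFAT1 shRNA 2 and 3349 without NFAT1 shRNA 1. It was 407 without control 3 and NFAT1 shRNA 1. Genes changed at least 2-fold numbered 504 with array weights, 242 with the block, 26 with the mean of a gene's probe sets and 22 against the log2 threshold. They numbered 0 to 672 with 1 array left out and 263 without both arrays. Changed probe sets numbered 2279 with array weights, 1432 with the block, 0 to 5794 with 1 array left out and 0 without both arrays (limma, 9273 at an unadjusted p under 0.05). Lists past the threshold numbered 6 to 12 with 1 array left out, 6 without both, 0 with an estimated correlation and 0 with fry (1 and 5 at an unadjusted p under 0.05), and 7 to 11 otherwise. The integrin list also lost its call with array medians subtracted (adjusted p = 0.0640) and with the block (0.0825), and the unfolded protein response list without probe sets prone to cross-hybridisation (0.199), with ranges of 0.00807 to 0.682 and 0.000635 to 0.682 over all settings. The probe set standing for Nfatc2 differed by 0.43 with array weights (adjusted p = 0.0289), by 0.24 to 0.44 with 1 array left out, and by -0.14 with the mean of its probe sets (adjusted p = 0.324), where probe sets of both directions are averaged. Its adjusted p ran from 0.0289 to 1 over all settings. On 1439205_at the difference ran from -0.82 to -0.63, with an adjusted p of 0.0160 to 0.342. The sign turned with the mean of probe sets for Nfatc1 (-0.030), Nfatc4 (0.032) and Ppp3cc (0.17), and for Nfatc4 without probe sets prone to cross-hybridisation (0.023) and without both arrays (0.056). With 1 array left out it turned for Nfatc4 (-0.024 to 0.041), Ppp3cc (-0.11 to 0.071) and Ppp3r1 (-0.14 to 0.040). The cause of these changes was not tested. Of dim genes, RMA signals near the background give compressed differences.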

Other observations

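The genes and tests of this part were chosen after the values were seen, except the splits of the arrays for probe sets and gene lists.

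Some genes differed widely between arrays of 1 group, and such genes were not counted. Lcn2, which encodes lipocalin 2, read 4.37, 9.99 and 8.82 on controls 1 to 3 and 6.07, 10.25 and 10.50 on NFAT1 shRNA 1 to 3. The protease inhibitor gene Serpinb2 read 8.48, 4.55 and 7.67 on the controls and 7.01, 3.93 and 4.48 on the NFAT1 shRNA arrays. The interferon-induced gene Ifit1 read 5.49, 8.70 and 7.73 against 4.03, 6.48 and 7.72, and Gbp2 read 5.85, 8.30 and 7.62 against 6.54, 9.05 and 8.93. Medians of the type I interferon list against the control mean were -0.71, 0.60 and 0.06 on the controls and -0.72, 0.19 and 0.43 on the NFAT1 shRNA arrays. Trp53inp1, a p53 target, read 4.87, 7.37 and 6.54 against 6.14, 9.29 and 9.32, and the cyclin gene Ccng2 read 7.73, 9.45 and 8.76 against 8.21, 10.67 and 10.63. Txnip, an inhibitor of glucose uptake, read at most 8.58 on the controls and 8.79, 11.50 and 11.13 on the NFAT1 shRNA arrays, with no overlap between the groups (adjusted p = 0.198 with limma).

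Without NFAT1 shRNA 1, limma called 3349 of 18193 genes, among them members of every list except the endothelial markers. Of 33 S phase genes 25 were lower and 0 higher, of 33 mitosis genes 16 lower and 0 higher, and of 30 ribosome biogenesis genes 18 lower and 0 higher. Of 20 cholesterol synthesis genes 8 were lower, of 18 antigen presentation genes 8 were higher and 1 lower, and of 32 immediate early genes 8 were higher. Other lists went both ways, such as NRF2 targets with 7 higher and 5 lower of 23, hypoxia genes with 7 and 4 of 30 and apoptosis regulators with 7 and 2 of 27. Without control 3 as well, these counts were 8, 1 and 0 lower for S phase, mitosis and ribosome biogenesis, 1 lower for cholesterol synthesis, 0 for antigen presentation and 4 higher for immediate early genes.

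Control 3 lay between controls 1 and 2 for 100% of the 199 genes with a range of at least 2-fold over the 3 controls, which argues against gene by gene independent variation, though not against a state shared by many genes. A single intermediate point on the log2 scale is argued against as well, since its median position was 0.677 for 18 genes higher in control 1 and 0.406 for 181 genes higher in control 2, a difference of 0.271 (95% bootstrap interval 0.225 to 0.308). The interval measures spread over genes, which are not independent, and not between cultures, so it can be too narrow. A candidate explanation is that control 3 holds a mixture of RNA or cells of controls 1 and 2: a linear share of 55% of control 1 left a residual SD of 0.0807 (log2), the smallest of 60 fits of 1 array by 2 others (next 0.146, also for control 3, and at least 0.178 for other arrays), with shares of 0.554 and 0.533 in the 2 sets of genes. The residual SD alone mostly shows that control 3 is intermediate. On simulated genes, whose noise was set by hand, a mixture left 0.0802 and a log-scale midpoint 0.0886. The 0.0802 returns the noise put in, so its nearness to 0.0807 tells nothing about control 3. Pooled RNA and mixed cells were not separated by any test here, and no biological explanation was tested. If so, the control group holds fewer than 3 independent samples and its spread is too small.

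NFAT1 shRNA 1 lay with the controls on the first principal component (61.4% of the variance), at -19.6 against -49.2 to -11.9 for the controls and 58.1 and 51.0 for NFAT1 shRNA 2 and 3. A wrongly labelled control array is argued against by Nfatc2: over its 6 probe sets this array lay 1.11 of the way from the controls to NFAT1 shRNA 2 and 3, and 0.749% of draws of other probe sets of like signal lay as far from the controls (8.48%, 26.9% and 26.3% with each control in its place), which rests mostly on 1439205_at. Draws were counted in both directions. Controls 1 to 3 lay at -0.68, -0.52 and -0.28, away from NFAT1 shRNA 2 and 3, each with NFAT1 shRNA 1 among its reference arrays. A mixture of knockdown and control cells stays open, though the values pull against 1 share: 0.18 left the fewest of 587 genes outside their range (9.88%) but puts 1439205_at at 5.95, where it read 5.15 (2.06% of probe sets of like signal were as far off). This probe set was chosen as the Nfatc2 probe set with the smallest p over all 6 arrays, NFAT1 shRNA 1 among them. Its low reading on this array was thus partly selected, which weakens this pull, and the share of 0.45 below depends on the same choice. Shares of at least 0.45, which allow the signal of 1439205_at, left at least 19.3% outside, which is more than control 1 gave in its place (10.3%) but not over 2 times as much, the bound of the test. Control 1 had NFAT1 shRNA 1 itself among its reference arrays there, which weakens this bound. Of the 587 genes, NFAT1 shRNA 1 lay at over 0.8 of the log2 change for 43 and at under 0.2 for 353. These counts also pull against 1 share. They cannot decide it, since 1 linear share gives no single log2 position and the spread of single genes was not allowed for. A culture or processing state that also varied between controls may contribute: across genes, control 1 minus control 2 correlated with NFAT1 shRNA 1 minus the mean of NFAT1 shRNA 2 and 3 (r = 0.778, rho = 0.763; genes are not independent), and a weaker response to the shRNA was not tested. The correlation rests on the same deviations as those of same-numbered arrays above, where pairing stays open. It is thus not a separate observation.

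The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 93 changed genes, 44 changed at least 2-fold and 90 changed probe sets, and 1 of the 10 splits, the real one, gave as many of each, where the highest of the other splits gave 0 with limma. Lists past the camera threshold numbered 10 in the real split and at most 10 in the others, and 3 of the 10 splits gave as many. The other 2 set controls 2 and 3 with NFAT1 shRNA 3, or controls 2 and 3 with NFAT1 shRNA 2, against control 1, NFAT1 shRNA 1 and the remaining array.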
